A study of Homo sapiens with 18 samples.

How the data were processed

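Gene expression was measured on 18 Affymetrix arrays from the human colorectal cancer lines WiDr and HT29. The labels placed the arrays in 6 groups of 3, namely WiDr with vehicle, with AZ628, with control shRNA and with IKKα shRNA, and HT29 with vehicle and with AZ628. The design text writes the inhibited arrays of the second line as HT28, which was read as HT29 from the sample labels. Per the labels' protocols, 100 ng of total RNA entered the labelling assay. They describe a whole-transcript sense assay, whereas the probe set names are of the kind used on arrays read from the 3′ end. This was not resolved, so the 3′ minus 5′ difference of the actin controls is given as a value and not read as RNA quality. The deposited value table holds log2 signals per probe set, which the authors made with RMA, per the submitters' processing notes, which also name limma and R 3.0.2. As a method RMA draws the arrays to a common distribution and compresses small signals, so a change shared by most transcripts is not visible and folds of dim genes are understated.

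The value table held 49395 probe sets, 102 of them controls. The probe table given for the platform tied 44994 to 1 gene symbol, 1832 to several and 2569, controls included, to none. Genes were named only from probe sets with 1 symbol, and each of the 18132 genes was represented by its probe set with the highest mean over all 18 arrays. No dim genes were left out. Probe sets of related genes can cross-hybridise, and where the probe sets of a named gene differed widely their range is given for the main cases.

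The values were analysed in R 4.3.3 with limma 3.58.1 and the data.table package, version 1.17.8, and figures were drawn in Python 3.11.15 with matplotlib 3.10.9. A linear model with 6 groups was fitted to all 18 arrays, so that the groups shared 1 estimate of the spread per gene (12 residual degrees of freedom, prior degrees of freedom 4.49), followed by eBayes with default settings and Benjamini-Hochberg adjustment over all genes within each contrast. The contrasts were AZ628 against vehicle in each line, IKKα shRNA against control shRNA, the difference of the AZ628 effects between the lines, the difference between the shRNA effect and the AZ628 effect in WiDr, HT29 against WiDr with vehicle, and control shRNA against vehicle in WiDr. IKKα shRNA against vehicle, and its difference from AZ628 with vehicle as the control of both, were added after the data were seen. Adjusted p-values of genes are limma's, two-sided. The overlap of independent lists is the product of both lists' sizes over the number of genes.

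A set of 27 gene lists with 492 entries, of which 455 were measured and the rest not analysed here, was written from textbook knowledge before the data were examined, together with the design, the alternatives and the rule for naming genes. The lists cover MAPK output, immediate early genes, receptor tyrosine kinases, EGF ligands, NF-κB targets and pathway members, DNA replication, mitosis, ribosome biogenesis, cholesterol synthesis, glycolysis, lysosome, absorptive and secretory markers, Wnt and stem cell genes, Notch, invasion, YAP targets, interferon response, unfolded protein response, ATF4 targets, p53 targets, the BCL2 family, fibroblast, blood and endothelial markers and housekeeping genes. Each list was tested against the other genes with camera at a preset correlation of 0.01 and with an estimated correlation, with adjustment over the lists of a contrast. In text the counts of members that rose or fell use the adjustment over all genes unless "adjusted over the list alone" is said.

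The rule for named genes took, per treatment, the 12 largest rises and 12 largest falls among passing genes whose treated arrays all lay on 1 side of the control arrays, the 10 largest differences for both difference contrasts, the 10 genes leading each overlap in the same direction and 5 in opposite directions, up to 4 passing and 2 other members of each list, and a fixed set of pathway genes. It passed over symbols of non-coding and provisional loci and probe sets naming several genes. Not every gene it selects is printed, and genes outside it are marked as chosen after their values were seen.

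The model was tested on simulated data, with 200 of 18132 genes changed in each comparison. At a 1.5-fold change it recovered 85.1% for AZ628 in WiDr, 88.1% for AZ628 in HT29, 89.6% for IKKα shRNA and 65.7% for the difference between lines, and at 2-fold 100% in the first 3 and 98.5% in the last. The false calls numbered 8, 13, 19 and 10. For AZ628 in WiDr, 1 of 1 shifted list was called and 0 of 20 unshifted lists. The simulated genes were drawn independently of each other. The list result therefore does not test how calls behave when genes of a list move together. The changed genes were also far fewer than those that passed in the data.

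The alternatives tried were a 2-fold minimum, every probe set as its own entry, the mean of a gene's probe sets, leaving out the dimmest 30% of genes, quantile normalization again, median centring and cyclic loess, eBayes with trend and robust settings, array weights, only the arrays of a comparison in the fit, the replicate number as a block, each array left out in turn, estimated correlation and fry for the lists, and, added after the data were seen, leaving out probe sets that can bind several transcripts and using vehicle in place of control shRNA.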

Results

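Gene expression was profiled on 18 arrays from 2 established human colorectal cancer lines, WiDr and HT29, in 6 groups of 3 arrays each. WiDr is regarded as a derivative of HT29. Both lines were sampled with vehicle and with AZ628, an inhibitor of RAF kinases, which pass growth signals from RAS to MEK and ERK. WiDr was sampled in addition with a control short hairpin RNA (shRNA) and with an shRNA against IKKα, the kinase encoded by CHUK that acts in NF-κB signalling. The design set inhibited against control cells in each line and IKKα shRNA against control shRNA in WiDr, and the series title relates RAF signalling, IKKα and NF-κB. The labels gave neither the dose nor the time of AZ628.

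Each array gave log2 signals for 49395 probe sets, from which 18132 genes were compared through 1 probe set each. Pearson correlations over the genes lay between 0.9971 and 0.9985 for arrays of the same group and between 0.9555 and 0.9963 for arrays of different groups, and no pair of arrays was identical. The first principal component, with 53.6% of the variance, separated the AZ628 arrays of both lines from all others, the second (22.0%) separated HT29 from WiDr, and the third (11.8%) set the IKKα shRNA arrays apart from the other WiDr arrays. The number of arrays, 3 in each group, limited the precision, and since the labels do not say that the arrays of a group came from separate cultures, the p-values measure only the spread between these arrays, which may be technical. All changes below are log2 differences between group means with their standard errors (SE) from limma, and a gene passed at an adjusted p under 0.05 over all 18132 genes.

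The transcript targeted by the shRNA was measured first. CHUK had a mean log2 signal of 9.64 ± 0.17 (SD, n = 3) with control shRNA and 7.52 ± 0.25 (SD, n = 3) with IKKα shRNA, a change of -2.12 (SE 0.12, adjusted p = 4.11e-10) that left the signal 4.33-fold lower. The 3 IKKα shRNA arrays read 7.68, 7.23 and 7.65, below every other array of the series, of which the lowest read 8.90. Against vehicle-treated WiDr the change was -1.97 (SE 0.12), and control shRNA differed from vehicle by 0.15 (SE 0.12, adjusted p = 0.401). IKBKB, which encodes IKKβ, the other catalytic subunit of the IKK complex, differed by 0.25 (SE 0.11, adjusted p = 0.0763, and 0.00555 with its probe sets averaged or 0.0369 with quantile normalization again), and IKBKG, which encodes the regulatory subunit NEMO, rose by 0.48 (SE 0.09), or by 0.18 (adjusted p = 0.00925) with its probe sets averaged. CHUK also changed with AZ628, by -0.43 in WiDr (SE 0.12, adjusted p = 0.00854) and -0.37 in HT29 (adjusted p = 0.0209). The WiDr call was lost without AZ628 replicate 3 (adjusted p = 0.0503) or without vehicle replicate 1 (adjusted p = 0.0537), and the HT29 call without AZ628 replicate 2 (adjusted p = 0.0787) or vehicle replicate 2 (adjusted p = 0.0806). Only 1 probe set was tied to CHUK.

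**Figure D1:**
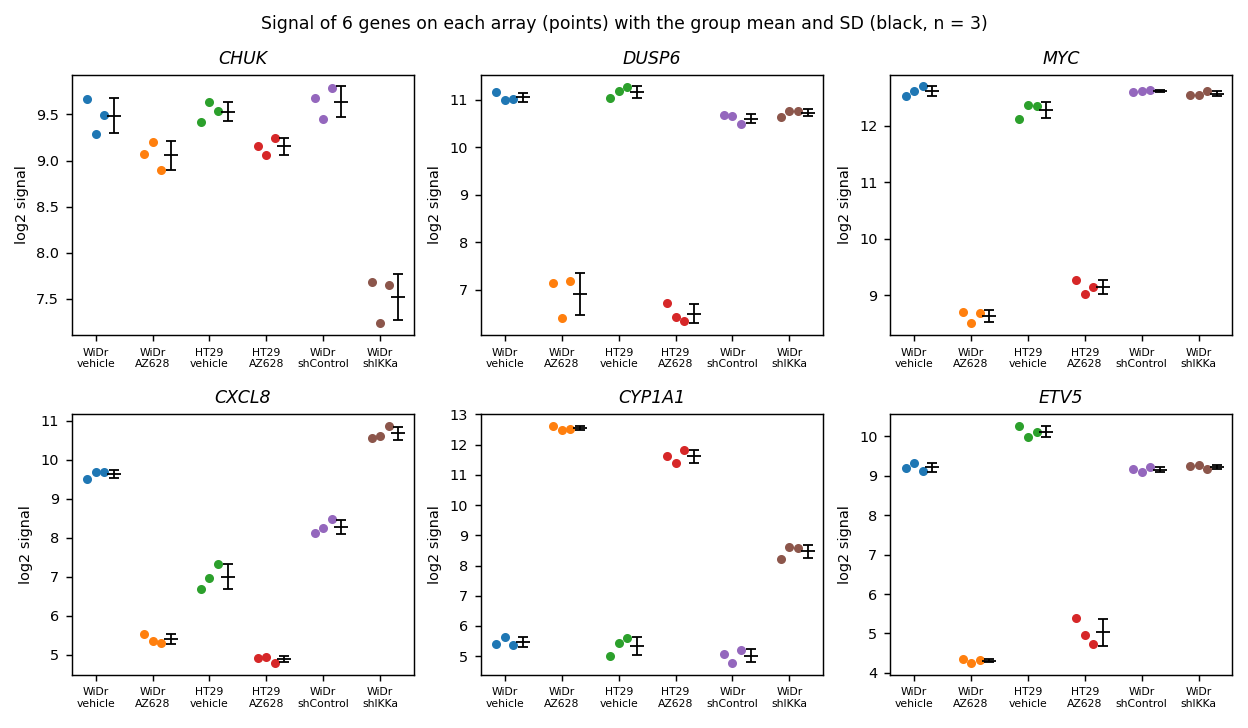
Log2 signal of CHUK, DUSP6, MYC, CXCL8, CYP1A1 and ETV5 (y axes) on each of the 18 arrays by group (x axes); points are arrays and black marks give the group mean and SD (n = 3). CHUK is lowest with IKKα shRNA (mean 7.52), DUSP6, MYC and ETV5 are low with AZ628 in both lines, and CXCL8 is low with AZ628 and highest with IKKα shRNA (mean 10.68).

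The first comparison asked how WiDr responded to the RAF inhibitor. Transcripts that follow ERK activity fell. ETV5, an ETS transcription factor downstream of ERK, fell by 4.90 (SE 0.12), DUSP6, the phosphatase that removes phosphate from ERK, fell by 4.14 (SE 0.16), and CCND1, cyclin D1, fell by 3.34 (SE 0.07). MYC, the transcription factor of growth and proliferation, fell by 3.98 (SE 0.08) to a signal 15.8-fold lower. The largest rise was in CYP1A1, a cytochrome P450 that oxidises aromatic compounds, whose mean log2 signal went from 5.47 to 12.54, a change of 7.07 (SE 0.15, adjusted p = 5.22e-16).

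In all, 8079 genes passed in WiDr, 4249 higher and 3830 lower with AZ628, and 80.5% of them changed less than 2-fold. At least 2-fold changes were seen in 784 genes that rose and 789 that fell. After CYP1A1, the largest rises included UGT2B15, a glucuronidating enzyme (5.53), NDRG1, a stress and differentiation gene (4.70), TENT5C (4.26), TP53INP1, a p53-inducible gene (4.19), PON1, paraoxonase 1 (4.18), and CYP1B1, another cytochrome P450 of the same family (3.95). The largest falls were in CEMIP, a hyaluronan-binding protein (-5.35), ETV5, CXCR4, a chemokine receptor (-4.85), MYEOV (-4.76), ETV1, another ETS factor (-4.50), and CXCL8, the chemokine interleukin 8 (-4.23, SE 0.13). LGR5, a receptor of intestinal stem cells, fell by 3.59. Probe sets of a gene differed in size of change: those of CEMIP ranged from -5.35 to -0.18, those of ETV1 from -4.50 to -0.20 and those of TP53INP1 from 0.09 to 4.19.

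Of the 27 gene lists, 9 moved as a group in WiDr with AZ628 by camera with its preset correlation. In the MAPK output list, 15 of 16 measured members fell, over all genes and adjusted over the list alone, with a median of -2.55, or 5.86-fold lower (camera adjusted p = 3.12e-14). The exception was the ephrin receptor gene EPHA4 (0.03, adjusted p = 0.91). All 27 measured DNA replication genes fell, also adjusted over the list alone (median -1.67, adjusted p = 3.26e-21), among them MCM10 (-2.48) and MCM6 (-2.36), a factor that activates the replicative helicase and a subunit of it. In the ribosome biogenesis list, 22 of 23 members fell, 23 adjusted over the list alone (median -1.73, adjusted p = 1.37e-18), including NOP16 (-2.86) and LYAR (-2.41), which encode nucleolar proteins. Glycolysis genes fell in 12 of 17 cases, 13 adjusted over the list alone, and 1 rose (median -0.45, adjusted p = 1.5e-05). They were led by hexokinase 2, HK2 (-2.80), and the glucose transporter SLC2A1 (-1.88). Lysosome and autophagy genes rose in 15 of 19 cases and 1 fell, or 15 and 2 adjusted over the list alone (median 0.56, adjusted p = 1.5e-05), with GABARAPL1 (1.71), which acts in autophagosome formation, and the sialidase NEU1 (1.66) in front. These 5 calls held with an estimated correlation.

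Of the 4 other lists that moved in WiDr with AZ628, none held with an estimated correlation. Mitosis genes fell in 20 of 25 cases, also adjusted over the list alone, with a median of -0.48 (adjusted p = 8.26e-07, and adjusted p = 0.0823 with an estimated correlation). Interferon response genes rose in 13 of 21 cases and 1 fell, the same counts as adjusted over the list alone (median 0.59, adjusted p = 4.18e-04, and adjusted p = 0.0823 with an estimated correlation), for example IFIT1 (1.35). ATF4 targets, genes of the integrated stress response, fell in 12 of 18 cases and rose in 4, also adjusted over the list alone (median -0.79, adjusted p = 0.00187, and adjusted p = 0.244 with an estimated correlation). The amino acid transporter gene SLC7A5 fell by 2.21 there, while DDIT4, an inhibitor of mTORC1, rose by 1.17. In the p53 target list 10 of 16 genes rose and 4 fell, also adjusted over the list alone (median 0.40, adjusted p = 0.025, and adjusted p = 0.13 with an estimated correlation). TP53INP1 (4.19) and SESN1 (2.15) led the rises, and CDKN1A, the p21 cell cycle inhibitor, differed by 0.14 (adjusted p = 0.336, and 0.0366 without vehicle replicate 2). The p53 call was also lost when the probe sets of a gene were averaged (adjusted p = 0.105) or dim genes left out (adjusted p = 0.0729).

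HT29 was given the same inhibitor to ask whether the other line responded alike. The ERK-dependent transcripts fell here as well, with changes of -5.09 (SE 0.12) in ETV5, -4.66 (SE 0.16) in DUSP6, -2.77 (SE 0.07) in CCND1 and -3.14 (SE 0.08) in MYC. CYP1A1 rose by 6.26 (SE 0.15). Next came GSTA1 (6.24) and GSTA2 (4.93), near-identical glutathione transferases that probe sets may not tell apart (GSTA1 was 0.13, adjusted p = 0.608, without probe sets that bind several transcripts), and sucrase-isomaltase, SI, a brush border enzyme of absorptive enterocytes (5.14). Alongside CEMIP (-5.14) the largest falls included CLDN2, a pore-forming claudin of tight junctions (-4.68), and NOX1, a colonic NADPH oxidase (-3.19).

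A total of 7898 genes passed in HT29, 4085 higher and 3813 lower, of which 588 rose and 726 fell at least 2-fold. The same 9 lists moved as in WiDr. All 16 MAPK output genes fell (median -2.28, adjusted p = 9.15e-16), as did all 27 DNA replication genes (median -1.92, adjusted p = 4.81e-25) and all 23 ribosome biogenesis genes (median -1.52, adjusted p = 5.67e-20), each also adjusted over the list alone. Mitosis genes fell in 22 of 25 cases (median -0.63, adjusted p = 1.17e-09) and glycolysis genes in 12 of 17 with 1 rise (median -0.54, adjusted p = 5.42e-06), the same adjusted over the list alone. Those 5 calls held with an estimated correlation. Lysosome genes rose in 13 of 19 cases and 2 fell, or 14 and 2 adjusted over the list alone (median 0.44, adjusted p = 2.4e-04, and adjusted p = 0.0555 with an estimated correlation). Interferon genes rose in 14 of 21 cases, 15 adjusted over the list alone (median 0.46, adjusted p = 7.51e-05, and adjusted p = 0.053 with an estimated correlation). ATF4 targets fell in 12 of 18 cases and 3 rose, also adjusted over the list alone (median -0.41, adjusted p = 0.0121, and adjusted p = 0.345 with an estimated correlation). In the p53 list 11 of 16 genes rose and 4 fell, or 11 and 5 adjusted over the list alone (median 0.48, adjusted p = 0.00825, and adjusted p = 0.0691 with an estimated correlation).

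The responses of the lines to AZ628 were then set against each other. Of the genes that passed in both lines, 3338 rose in both and 3091 fell in both, against 957.3 and 805.4 for independent lists of these sizes, while 40 rose in WiDr and fell in HT29 and 51 did the reverse. At 2-fold, 448 genes rose and 606 fell in both lines and 0 went opposite ways. Over all genes the log2 changes correlated with a Pearson r of 0.891 and a Spearman rho of 0.797, where genes are not independent replicates. Among the 1573 genes changed at least 2-fold in WiDr, 99.2% had the same sign in HT29 and the slope was 0.809. The comparisons share no arrays.

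The difference between the responses was tested directly as the AZ628 effect in HT29 minus that in WiDr, and 1667 genes passed, 736 above 0 and 931 below, of which 175 differed at least 2-fold. PON1 rose by 4.18 in WiDr and by 0.42 in HT29, a difference of -3.76 (SE 0.12, adjusted p = 5.2e-12). NNMT, a nicotinamide-methylating enzyme, fell by 3.78 in WiDr and differed by -0.02 (adjusted p = 0.952) in HT29, where its vehicle signal was already low at 4.29, so that the difference was 3.76 (SE 0.22). UNC93A rose by 3.79 in HT29 and by 0.32 in WiDr, CLDN2 changed by -4.68 in HT29 and -1.68 in WiDr, and the chloride channel gene ANO1 by -0.80 in HT29 and -3.67 in WiDr. The ANO1 difference was 1.85 (adjusted p = 1.38e-09) with its probe sets averaged, but 0.04 (adjusted p = 0.93) without probe sets that bind several transcripts. That of GSTA1 was 1.16 (adjusted p = 0.000557) and -0.14 (adjusted p = 0.832) in the same settings. CXCL8 fell less in HT29 (-2.11, or -0.56 without probe sets that bind several transcripts) than in WiDr (difference 2.12, SE 0.19), but it started from a lower vehicle signal in HT29 (7.005 against 9.629) and the signals with AZ628 were low in both, 4.894 and 5.402. A few genes passed in opposite directions, among them the bicarbonate transporter gene SLC4A4 (0.97 in WiDr, -1.10 in HT29), TGFBR3 (0.95 and -1.04) and PTGS2, which encodes cyclooxygenase 2 (-1.18 and 0.71). With probe sets averaged SLC4A4 was 0.30 and -0.62, PTGS2 was -0.56 and 0.34, and TGFBR3 was -0.61 in HT29. These values still passed. With the preset correlation 6 lists differed between the lines. DNA replication fell further in HT29 (median difference -0.25, adjusted p = 2.53e-06, and adjusted p = 0.271 with an estimated correlation), with 7 of 27 genes passing below 0 and 1 above, or 14 and 1 adjusted over the list alone. Cholesterol synthesis differed by a median of -0.23 (adjusted p = 0.00442, and adjusted p = 0.0659 with an estimated correlation). The other calls, mitosis, lysosome, secretory markers and ribosome biogenesis, had median differences of -0.14, -0.10, 0.13 and 0.06 and were lost too, with adjusted p = 0.605, 0.271, 0.271 and 0.569 with an estimated correlation.

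**Figure D2:**
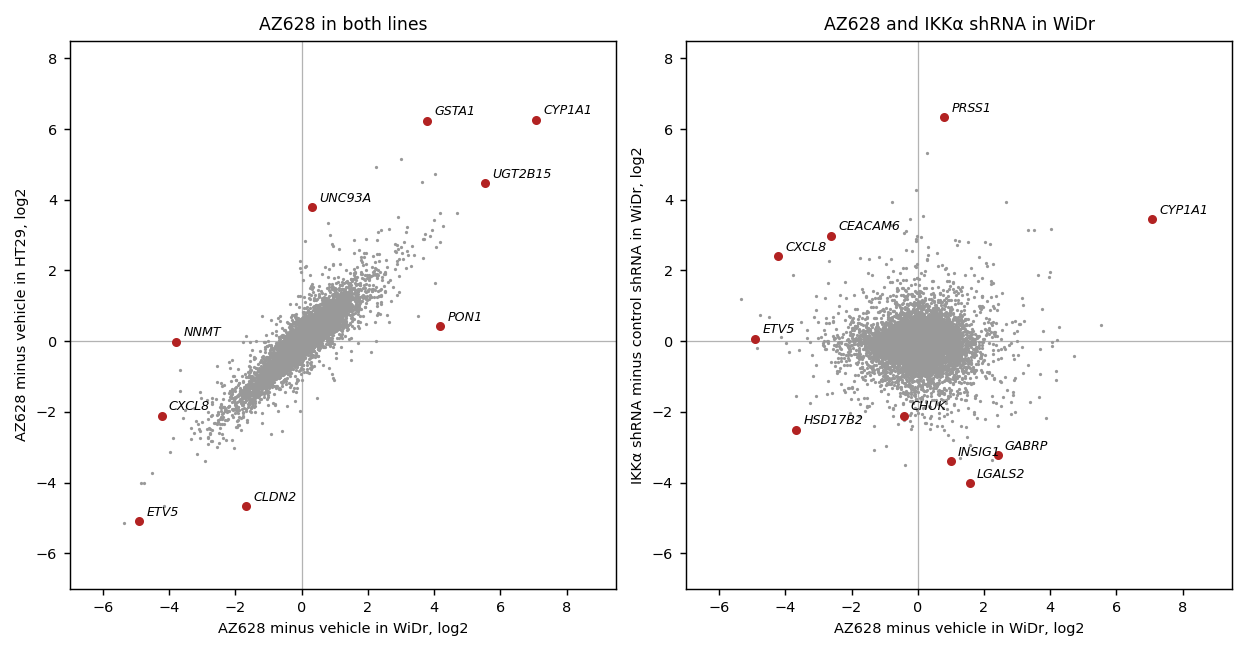
Log2 differences of all 18132 genes (grey points), AZ628 minus vehicle in WiDr (x axes) against AZ628 minus vehicle in HT29 (left, y axis) and against IKKα shRNA minus control shRNA in WiDr (right, y axis); named genes are red. On the left the points follow a diagonal (Pearson r 0.891) with PON1, NNMT, UNC93A and CLDN2 off it, and on the right they do not (Pearson r -0.0012).

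The third comparison asked which genes changed when IKKα was knocked down in WiDr. PRSS1, which encodes the digestive protease trypsinogen, rose by 6.34 (SE 0.11, adjusted p = 9.44e-17), and SPRR1B, a cornified envelope protein of squamous epithelia, by 5.32 (SE 0.14). The retinoid enzyme genes DHRS9 (3.93) and ALDH1A3 (3.14), the serpin SERPINB7 (4.27), the surface protein gene CEACAM5 (3.28) and CYP1A1 (3.45) rose as well. INSIG1, which restrains the SREBP regulators of sterol synthesis, fell by 3.40 (SE 0.10), and REG4, a secreted lectin of secretory intestinal cells, fell by 3.07 (SE 0.07). The ERK-dependent genes named above did not pass: DUSP6 differed by 0.12 (adjusted p = 0.601), ETV5 by 0.07 (adjusted p = 0.687), CCND1 by 0.09 (adjusted p = 0.334) and MYC by -0.04 (adjusted p = 0.759). CCND1 passed with its probe sets averaged (0.27, adjusted p = 0.00108) and against vehicle (0.62, adjusted p = 1.39e-06).

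A total of 6321 genes passed, 2879 higher and 3442 lower with IKKα shRNA, and 89.2% of them changed less than 2-fold. At 2-fold 276 rose and 408 fell. The 2 largest falls, in the lectin gene LGALS2 (-4.02) and the annexin gene ANXA13 (-3.52), were measured against control shRNA arrays in which both genes were higher than with vehicle, by 2.88 and 2.34. Against vehicle LGALS2 differed by -1.14 and ANXA13 by -1.18. PRSS1 was 6.15, SPRR1B 4.81, CYP1A1 3.00, INSIG1 -2.99 and REG4 -1.99 against vehicle. The PRSS1 probe sets ranged from 0.32 to 6.34 and can bind related trypsinogen genes.

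By camera with the preset correlation 8 lists moved with IKKα shRNA. ATF4 targets rose in 15 of 18 cases, also adjusted over the list alone (median 1.30, 2.46-fold, adjusted p = 6.02e-12). DDIT4 (2.71), VLDLR (2.30), ASNS, asparagine synthetase (2.19), and SLC7A5 (1.68) were the foremost, at 1.75, 2.62, 1.28 and 1.47 against vehicle. Cholesterol synthesis genes fell in 12 of 14 cases, also adjusted over the list alone (median -0.78, adjusted p = 8.55e-10). After INSIG1 the largest falls were in MSMO1 (-1.90) and HMGCS1 (-1.36, or -0.66 against vehicle), enzymes of the pathway. Interferon response genes fell in 14 of 21 cases, also adjusted over the list alone (median -0.50, adjusted p = 7.45e-08), led by IFI44 (-2.40) and MX1 (-1.61), of which IFI44 stayed lower against vehicle (-0.65) and MX1 was 0.69. With vehicle arrays in place of control shRNA the ATF4 list kept its direction (median 0.93), as did cholesterol synthesis (median -0.51), whereas the interferon list turned, with a median of 0.30 (adjusted p = 5.94e-05). Invasion and mesenchymal genes rose in 12 of 21 cases and 2 fell, also adjusted over the list alone (median 0.28, adjusted p = 5.93e-04), with the urokinase gene PLAU (2.58), fibronectin, FN1 (2.33), and, chosen after its value was seen, vimentin, VIM (1.10). Secretory cell markers fell in 8 of 15 cases and 1 rose, or 8 and 2 adjusted over the list alone (median -0.48, adjusted p = 5.93e-04), with REG4 and the trefoil factor TFF3 (-1.74, or -0.95 against vehicle). Against vehicle the secretory call was lost (median -0.11, adjusted p = 0.091).

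Those 5 calls held with an estimated correlation and the other 3 did not. DNA replication genes fell in 19 of 27 cases, also adjusted over the list alone (median -0.36, adjusted p = 5.92e-07, and adjusted p = 0.125 with an estimated correlation). Mitosis genes fell in 16 of 25 cases, 20 adjusted over the list alone (median -0.29, adjusted p = 7.05e-06, and adjusted p = 0.125 with an estimated correlation). Lysosome genes rose in 12 of 19 cases and 3 fell, also adjusted over the list alone (median 0.25, adjusted p = 0.00393, and adjusted p = 0.125 with an estimated correlation). The MAPK output list was not called (median 0.11, adjusted p = 0.232): 7 of 16 genes rose and 2 fell, the same as adjusted over the list alone, with ETV1 at 0.70 (0.23, adjusted p = 0.287, against vehicle) and the ERK pathway inhibitor SPRED1 at -1.12. The p53 targets were not called either (median -0.47, adjusted p = 0.0703): 9 of 16 genes fell and 4 rose, the same as adjusted over the list alone. That list passed without probe sets that bind several transcripts (adjusted p = 0.0241) and without control shRNA replicate 1 (adjusted p = 0.0456).

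**Figure D3:**
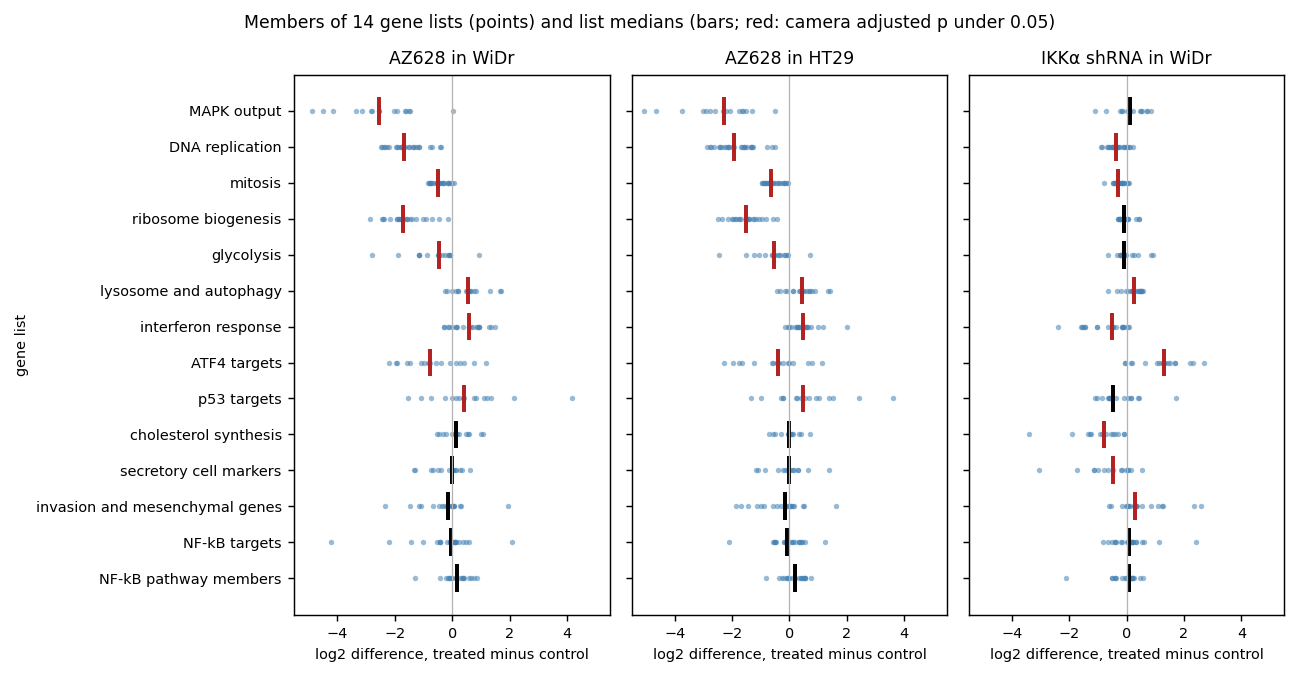
Log2 differences (x axes) of the members of 14 gene lists (y axis; blue points) with AZ628 in WiDr, AZ628 in HT29 and IKKα shRNA in WiDr; bars are list medians, red where the camera adjusted p was under 0.05. MAPK output, DNA replication and ribosome biogenesis lie far below 0 with AZ628 in both lines (WiDr medians -2.55, -1.67 and -1.73), and ATF4 targets lie above 0 with IKKα shRNA (median 1.30).

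Because the title joins RAF signalling to IKKα, the IKKα shRNA changes were set against those of AZ628 in WiDr. A total of 1052 genes rose in both and 1195 fell in both, against 674.7 and 727 for independent lists. A further 1401 rose with AZ628 and fell with IKKα shRNA (independent 806.6) and 764 did the reverse (independent 608.1). At 2-fold 63 rose and 50 fell in both, and 88 and 33 went opposite ways. Over all genes the Pearson r was -0.0012 and the Spearman rho 0.0171, and of the 1573 genes changed 2-fold by AZ628, 50.5% had the same sign with IKKα shRNA. Genes that moved the same way were CYP1A1 (7.07 with AZ628, 3.45 with IKKα shRNA), JAKMIP2 (4.03 and 3.19), SERPINI1 (3.32 and 3.16), ALDH1A3 (3.51 and 3.14), the heme oxygenase gene HMOX1 (2.18 and 2.76), the aldo-keto reductase AKR1C1 (2.27 and 2.19) and the steroid dehydrogenase HSD17B2 (-3.68 and -2.50). Genes that moved apart were CXCL8 (-4.23 and 2.40), CEACAM6 (-2.61 and 2.98), AKAP12 (-2.69 and 2.28), the GABA receptor subunit GABRP (2.41 and -3.23) and SLC3A1 (2.41 and -2.41). Without probe sets that bind several transcripts SLC3A1 passed in neither (0.17, adjusted p = 0.344, and -0.14, adjusted p = 0.49). CEACAM6 was -1.06 with AZ628 when its probe sets were averaged, and CXCL8 was 1.05 with IKKα shRNA against vehicle.

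The difference itself, IKKα shRNA effect minus AZ628 effect, passed for 7687 genes, 3639 above 0 and 4048 below, led by CXCL8 (6.62, SE 0.19) and CEMIP (6.54, SE 0.18). By camera with the preset correlation 10 lists differed, 6 above 0 and 4 below. MAPK output differed by a median of 2.50 (camera adjusted p = 1.02e-12), ribosome biogenesis by 1.73 (adjusted p = 2.47e-15), DNA replication by 1.27 (adjusted p = 4.19e-14), ATF4 targets by 2.06 (adjusted p = 2.08e-11), invasion and mesenchymal genes by 0.48 (adjusted p = 2.94e-04) and glycolysis by 0.36 (adjusted p = 4.89e-04). The other way lay interferon response genes (median -1.24, adjusted p = 1.54e-09), cholesterol synthesis (median -0.87, adjusted p = 2.89e-07) and p53 targets (median -0.73, adjusted p = 0.00219). Those 9 calls held with an estimated correlation, and that of lysosome genes did not (median -0.27, adjusted p = 0.0109, and adjusted p = 0.169 with an estimated correlation). The shRNA effect in this difference is taken against control shRNA, in which the interferon list lay 1.30 above vehicle. With vehicle as the control of both effects, an alternative chosen after the data were seen, the interferon and lysosome calls were lost (medians -0.13 and -0.24, adjusted p = 0.837 and 0.0938), cholesterol synthesis was -0.65 (adjusted p = 4.23e-04), glycolysis 0.59 (adjusted p = 2.01e-05), and p53 targets were -0.68 (adjusted p = 0.0311, and adjusted p = 0.137 with an estimated correlation). In all 3 treatment comparisons 884 genes rose and 1008 fell.

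The NF-κB lists bear on the NF-κB part of the title. Canonical NF-κB targets were called in none of the 3 treatments (camera adjusted p = 0.728, 0.984 and 0.689 for AZ628 in WiDr, AZ628 in HT29 and IKKα shRNA). No list of targets of other NF-κB branches was tested, and camera asks for a shift in 1 direction. Of 24 measured targets 6 rose and 8 fell in WiDr with AZ628, 7 rose and 7 fell in HT29, and 5 rose and 6 fell with IKKα shRNA. Adjusted over the list alone the counts were 6 and 8, 7 and 7, and 7 and 6. Single members moved far. CXCL8 rose by 2.40 (SE 0.13) with IKKα shRNA, but by 1.05 against vehicle, since control shRNA differed from vehicle by -1.35. CXCL3 rose by 1.11 and CXCL1 by 0.61, both chemokines, although against vehicle CXCL3 was 0.55 and CXCL1 was -0.34 (adjusted p = 0.0437), while lower signals were seen for TNFAIP2 (-0.84), CCL20 (-0.64), NFKB1, the gene of p105 and p50 (-0.50, SE 0.05, and -0.28 against vehicle), and NFKBIA, which encodes the inhibitor IκBα (-0.40, SE 0.07). TNFAIP2 was -0.43 against vehicle and did not pass with its probe sets averaged (-0.07, adjusted p = 0.501) or without those that bind several transcripts (0.23, adjusted p = 0.108). TNFAIP3, the A20 feedback inhibitor, rose with AZ628 by 2.09 in WiDr and 1.25 in HT29 and differed by 0.22 (adjusted p = 0.0549) with IKKα shRNA, where it passed in several other settings, for example at 0.37 (adjusted p = 0.00235) against vehicle. Without probe sets that bind several transcripts its rises with AZ628 were 1.20 in WiDr and 0.62 in HT29. RELA differed by 0.11 (adjusted p = 0.273, and 0.0232 against vehicle), RELB by 0.21 (adjusted p = 0.199) and NFKB2 by 0.18 (adjusted p = 0.131, and 0.0465 with array weights or 0.0367 without IKKα shRNA replicate 3) with IKKα shRNA. The list of pathway members was not called in any of the 3 either (adjusted p = 0.264, 0.278 and 0.63). Besides CHUK it held MAP3K14, the NIK kinase upstream of IKKα, which rose by 0.56 (SE 0.07) with IKKα shRNA, or by 0.20 (adjusted p = 0.0132) with its probe sets averaged.

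The untreated lines differed, although WiDr is regarded as a derivative of HT29. Vehicle-treated HT29 and WiDr differed in 5836 genes, 3070 higher and 2766 lower in HT29, with 488 at least 2-fold apart. HT29 had more FABP1, a fatty acid binding protein of enterocytes (4.01, SE 0.10), and less FOS (-2.18, SE 0.19) and EGR1 (-1.78, SE 0.17), early transcription factors of the growth factor response, as well as CXCL8 (-2.62, SE 0.13). Within WiDr, control shRNA also lay below vehicle in FOS (-1.50), EGR1 (-2.22) and CXCL8 (-1.35). For these genes a state of the WiDr vehicle arrays cannot be told from a difference between the lines. Of 20 immediate early genes 15 were lower in HT29, 16 adjusted over the list alone (median -0.80, adjusted p = 6.25e-09). Absorptive cell markers were higher in 8 of 24 cases and lower in 2, or 10 and 2 adjusted over the list alone (median 0.19, adjusted p = 0.00322), and NF-κB targets lower in 10 of 24 and higher in 2, or 11 and 2 adjusted over the list alone (median -0.14, adjusted p = 0.00708). Glycolysis genes were higher in HT29 (median 0.16, adjusted p = 0.00671). Those 4 of 10 calls held with an estimated correlation. The other 6, interferon response, mitosis, cholesterol synthesis, ATF4 targets, YAP targets and the unfolded protein response, had median differences of -0.30, -0.10, 0.28, -0.18, -0.13 and 0.24 and were lost, with adjusted p = 0.0994, 0.342, 0.0645, 0.324, 0.0738 and 0.304 with an estimated correlation.

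Control shRNA was compared with vehicle in WiDr as background to the IKKα shRNA comparison. The hairpin, the vehicle and any batch cannot be told apart in this contrast. The same holds for every value of IKKα shRNA against vehicle. The interferon response list was higher with control shRNA in 17 of 21 cases, also adjusted over the list alone, by a median of 1.30, or 2.46-fold (camera adjusted p = 3.17e-26), with IFI27 (2.51, SE 0.08), MX1 (2.31, SE 0.13) and IFI44 (1.75, SE 0.08). EGR1 (-2.22, SE 0.17) and FOS (-1.50, SE 0.19) were lower. Of the 9 lists called, 6 held with an estimated correlation, namely the interferon list and 5 more that were higher with control shRNA: cholesterol synthesis (median 0.29, adjusted p = 4.83e-06), secretory markers (0.09, adjusted p = 0.0011), absorptive markers (0.12, adjusted p = 0.00611), glycolysis (0.12, adjusted p = 0.00611) and receptor tyrosine kinases (0.17, adjusted p = 0.0104). Immediate early genes (median -0.16, adjusted p = 0.00483, and adjusted p = 0.278 with an estimated correlation), ATF4 targets (median -0.26, adjusted p = 0.00505, and adjusted p = 0.278 with an estimated correlation) and DNA replication (median 0.12, adjusted p = 0.00611, and adjusted p = 0.405 with an estimated correlation) did not. Where the control moved opposite to the IKKα shRNA effect, as for cholesterol synthesis and ATF4 targets, it adds to that effect. In all 4023 genes passed, 2099 higher and 1924 lower, but only 71 at least 2-fold. The count was 2309 without vehicle replicate 2 and 2614 without vehicle replicate 3, and 6475 with array weights, and centring the arrays on their medians moved the split to 2392 higher and 1366 lower. The 18S ribosomal RNA control probe set read 11.14 ± 0.12 (SD, n = 3) with vehicle, 12.78 ± 0.86 (SD, n = 3) with control shRNA and 12.70 ± 0.25 (SD, n = 3) with IKKα shRNA, and the actin 3′ minus 5′ log2 difference was 2.01 on vehicle replicate 1 against 1.44 and 1.36 on the other vehicle arrays.

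**Figure D4:**
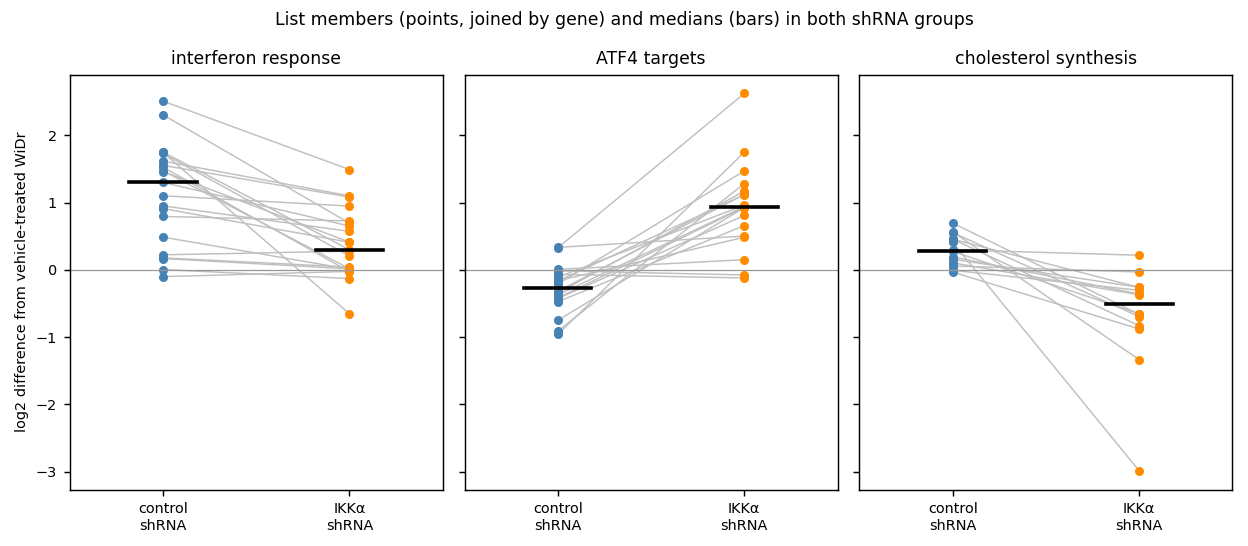
Log2 difference from vehicle-treated WiDr (y axis) of each member of 3 gene lists with control shRNA (blue) and IKKα shRNA (orange), joined by gene; bars are list medians. The interferon list lies above 0 in both groups (medians 1.30 and 0.30), ATF4 targets go from -0.26 to 0.93 and cholesterol synthesis from 0.29 to -0.51.

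The lists of markers of other cell types were called in none of the 3 treatments. Fibroblast, blood cell and endothelial lists had camera adjusted p-values between 0.268 and 0.984. The fibroblast gene LUM alone rose in all 3 (1.25, 1.77 and 2.84, SE 0.12 each), and CD14 of the blood list fell in all 3 (-0.96, -0.46 and -1.25). Against vehicle the CD14 change with IKKα shRNA was -0.53. Housekeeping genes were not called either (adjusted p = 0.241, 0.137 and 0.721), with medians of -0.06, -0.08 and -0.03.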

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

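The tests of the interferon and ATF4 patterns, and the regroupings with additive effects subtracted, were chosen after those results were seen. The other regroupings were planned.

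The response to AZ628 differed between the lines for 1667 genes by a test of the difference. The effect in HT29 minus that in WiDr was -3.76 for PON1, 3.76 for NNMT, 3.47 for UNC93A, -2.99 for CLDN2, 2.87 for ANO1, -2.80 for ALDH1A3, 2.72 for CYP4X1, 2.69 for GSTA2, 2.55 for BTNL8 and 2.46 for GSTA1, of which ANO1 (0.04) and GSTA1 (-0.14) did not pass without probe sets that bind several transcripts, a setting also chosen later. The NNMT signal was already low in HT29 with vehicle, which limits how far it could fall there. When the line labels were exchanged among the arrays of each treatment, 12 of 100 exchanges gave as many genes, and the highest other count was 7370. Exchanges that mix the lines on 1 side carry the baseline difference between WiDr and HT29 into the contrast, a structure of the samples, so these counts do not exclude chance. After the additive line and treatment effects were subtracted, only the real arrangement, 1 of 100, gave as many, and the highest other count was 3. On that footing the difference exceeded the spread between these arrays, which is all that the exchange measures. For the shRNA effect minus the AZ628 effect, 3 of 100 exchanges gave at least the observed 7687 genes (highest other 9964), and 1 of 100 after the subtraction (highest other 3729). Exchanges that call many genes again show the structure of the samples, so these counts do not exclude chance either. Arrays of a group may be technical repeats, so no exchange of arrays can exclude chance differences between cultures or batches.

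The comparisons of 3 arrays with 3 allow 10 splits, too few for a share under 0.05. In each of them 1 split, the real one, gave as many genes, with 8079 for AZ628 in WiDr, 7898 for AZ628 in HT29, 6321 for IKKα shRNA, 5836 for the untreated lines and 4023 for control shRNA against vehicle, and the highest other count was 0 in every case.

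Interferon response genes were lower with IKKα shRNA than with control shRNA (list median -0.50). The tables argue against IKKα shRNA having pushed the list as a whole below the level of vehicle-treated cells, since against vehicle the list median was 0.30, with 17 of 21 genes above 0, although IFI44 stayed lower at -0.65. The control shRNA arrays stood 1.30 above vehicle, with 20 of 21 genes above 0, so a raised control may account for the direction of the list's fall, though not for IFI44 lying below vehicle. What stays open is whether the hairpins differ in how far they evoke an interferon response or whether loss of IKKα damped one. With 1 control hairpin group these cannot be separated, and the biological explanation remains untested. A batch difference between the shRNA and vehicle arrays cannot be told apart from these either.

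ATF4 targets were higher with IKKα shRNA than with control shRNA (list median 1.30). A control shRNA group that had fallen below vehicle could produce such a rise, and the control list median did lie at -0.26. Against vehicle the IKKα shRNA list was still 0.93 higher, with 16 of 18 genes above 0. Measured from vehicle, a lowered control was therefore not the whole of the rise. That comparison cannot exclude it, because a batch difference between the shRNA and vehicle arrays cannot be told apart there. An effect of the hairpin on other transcripts, a difference in culture state and the loss of IKKα itself stay open and untested, and the labels do not state that more than 1 hairpin was used.

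Signals outside the gene comparisons moved as well. Among probe sets not tied to a single gene, 257 changed at least 2-fold with AZ628 in WiDr, 207 with AZ628 in HT29 and 111 with IKKα shRNA. The ribosomal RNA control probe sets were higher with control shRNA than with vehicle, by 1.64 for 18S and 0.86 for 28S on the log2 scale. Single outlying arrays were not tested within groups of 3, and fits without each array in turn stand with the other settings.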

How the results depend on the processing

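The alternatives with vehicle in place of control shRNA and without probe sets that bind several transcripts were chosen after the data were seen. The 2-fold counts under other settings were not planned either. A minimum of 2-fold left 1573 genes for AZ628 in WiDr, 1314 for AZ628 in HT29, 684 for IKKα shRNA, 175 for the difference between lines, 2168 for the shRNA effect minus the AZ628 effect, 488 for the untreated lines, 71 for control shRNA against vehicle, and 1054 and 113 genes changed the same way in both lines and by both treatments of WiDr, since it asks for more. Counting every probe set gave 19354, 18871, 14634, 2716, 18120, 13057, 8307, 14910 and 4863 in the same order, since genes have several probe sets, and 3517, 2856, 1543, 363, 5081, 1037 and 151 at least 2-fold for the first 7. Array weights raised control shRNA against vehicle from 4023 to 6475 genes, and leaving out vehicle replicate 2 or 3 lowered it to 2309 or 2614; the cause was not tested. Median centring moved its split from 2099 higher and 1924 lower to 2392 and 1366. With each array left out in turn the counts ranged from 7549 to 7770, 7347 to 7517, 5519 to 5970, 1309 to 1519, 7283 to 7673, 5136 to 5500 and 2309 to 4170 for the 7 comparisons in that order, and from 6121 to 6277 and 1987 to 2177 for the genes changed the same way. Every other setting run left these counts within 1.5 times, but averaging the probe sets of a gene took the 2-fold counts to 111 for the difference between lines and 44 for control shRNA against vehicle.

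With an estimated correlation the lists called fell from 9, 9, 8 and 6 to 5, 5, 5 and 0 for AZ628 in WiDr, AZ628 in HT29, IKKα shRNA and the difference between lines, and with fry, which asks only whether a list moves, the first 3 were 23, 20 and 25. The interferon list reversed with vehicle as the control, with a median of 0.30 in place of -0.50, because control shRNA itself lay above vehicle, and MX1 (0.69) turned with it. CXCL1 (-0.34) turned as well, but there control shRNA lay below vehicle. Without probe sets that bind several transcripts, other probe sets stood for ANO1 with AZ628 in HT29 (0.0367), GSTA1 in the difference between lines (-0.14), and ERBB3 (0.18) and TNFAIP2 (0.23) with IKKα shRNA. The sign of these values turned, but none of them passed (adjusted p = 0.812, 0.832, 0.17 and 0.108), so the calls were lost rather than reversed. Of 192 gene values 168 kept their call in every setting and 24 did not, and of 75 list results 58 did and 17 did not. Of the gene values that passed, 56 of 177 were over 1.5 times smaller or turned with probe sets averaged, 18 of 160 without probe sets that bind several transcripts and 18 of 58 against vehicle, and none grew by that much, so the sizes of single genes lean on the probe set and the control. The CHUK change with IKKα shRNA kept its call under every setting run, between -2.21 and -1.97.

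The replicate numbers shared between groups did not pair the arrays: same-numbered arrays had correlations of their deviations between -0.233 and 0.178, and in no comparison were all 3 over 0.1 (IKKα shRNA 0.041, 0.068 and 0.088) or did every array correlate best with its own number. A fit with the replicate number as a block (replicate block) gave 7854 genes for AZ628 in WiDr, 7618 for AZ628 in HT29, 5886 for IKKα shRNA, 1209 for the difference between lines and 7371 for the shRNA effect minus the AZ628 effect, and it ended or turned none of the 14 comparison values tested with it.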

Other observations

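The settings with vehicle in place of control shRNA and without probe sets that bind several transcripts were chosen after the data were seen, as was the gene SPP1, which lies outside the rule for naming genes. AHRR, TIPARP and CYP1A2 also lie outside it and were chosen after CYP1A1 and CYP1B1 were seen but before their own values were.

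Lists not described in the results moved in single members. Immediate early genes were called in none of the 3 treatments (camera adjusted p = 0.63, 0.642 and 0.348 for AZ628 in WiDr, AZ628 in HT29 and IKKα shRNA), yet the phosphatase gene DUSP5 fell with AZ628 (-2.70 and -2.52) and rose with IKKα shRNA by 1.64, and PTGS2 rose with IKKα shRNA by 2.37. Receptor tyrosine kinase genes were not called (adjusted p = 0.871, 0.984 and 0.813). ERBB3 rose with AZ628 (1.26 in WiDr, 0.92 in HT29) and fell with IKKα shRNA (-1.16). The fall was -0.64 (adjusted p = 4.31e-08) with its probe sets averaged. Without probe sets that bind several transcripts the changes of ERBB3 in WiDr were 0.23 (adjusted p = 0.0654) with AZ628 and 0.18 (adjusted p = 0.17) with IKKα shRNA. In HT29 its rise still passed in that setting (0.43, adjusted p = 0.00122). FGFR3 fell with IKKα shRNA by 2.08. The EGF receptor ligand gene EREG fell with AZ628 (-1.39 and -0.90) and rose with IKKα shRNA (1.87), in a list that was not called (adjusted p = 0.914, 0.984 and 0.232). The HT29 call of EREG was lost with its probe sets averaged (adjusted p = 0.079). In the BCL2 family (adjusted p = 0.643, 0.984 and 0.466) the pro-apoptotic gene BMF rose in all 3, by 3.14, 3.08 and 1.21, or by 0.99, 0.92 and 0.39 with its probe sets averaged. FGFR3 was -0.97 with its probe sets averaged.

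Absorptive cell markers were not called (adjusted p = 0.728, 0.984 and 0.449) and moved both ways: SI rose with AZ628 (2.99 and 5.14) while KRT20, a keratin of differentiated colonocytes, fell (-1.22 and -1.10), and FABP1 rose with AZ628 (2.82 in WiDr and 2.04 in HT29) and fell with IKKα shRNA (-2.05, or -0.77 against vehicle). Among Wnt and stem cell genes (adjusted p = 0.871, 0.984 and 0.913) LGR5 fell with AZ628 (-3.59 and -2.19) and AXIN2, a Wnt feedback gene, rose (1.43 and 1.36). Notch genes (adjusted p = 0.914, 0.984 and 0.63) included the ligand JAG1, which fell with AZ628 (-2.34 and -1.46) and rose with IKKα shRNA (1.30). With probe sets averaged the AZ628 changes in WiDr and HT29 were 1.72 and 3.08 for SI, 0.83 and 0.85 for AXIN2 and -1.35 and -0.81 for JAG1, and that of LGR5 in WiDr was -2.13. YAP targets (adjusted p = 0.166, 0.323 and 0.0883) and the unfolded protein response (adjusted p = 0.0803, 0.137 and 0.322) were not called, although the latter passed for AZ628 in WiDr after quantile normalization again (adjusted p = 0.0386) and for AZ628 in both lines after cyclic loess (adjusted p = 0.0276 in WiDr and 0.0243 in HT29), and the former with vehicle in place of control shRNA (adjusted p = 0.0136). Between the untreated lines the largest difference was in SPP1, osteopontin, 6.32 higher in HT29 (SE 0.12).

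CYP1A1 and CYP1B1, textbook targets of the aryl hydrocarbon receptor, rose with AZ628 in both lines, and if receptor activity were the source, other targets should rise too. Of AHRR, TIPARP and CYP1A2, 2 rose in both lines, AHRR by 2.83 and 2.54 (1.45 and 1.27 with its probe sets averaged) and TIPARP by 0.95 and 0.75, and CYP1A2 differed by 0.26 (adjusted p = 0.085) and 0.30 (adjusted p = 0.051). CYP1A2 passed in HT29 in several other settings, for example with array weights (adjusted p = 0.0158), and in WiDr without vehicle replicate 2 (adjusted p = 0.0154). Its change over the settings ranged from 0.0074 to 0.39 in HT29, with adjusted p up to 0.97. In WiDr it ranged from 0.11 to 0.38, with adjusted p up to 0.464. This is consistent with receptor activity as a hypothesis, whether through the compound itself or through the loss of RAF signalling, which no group of the series separates. With IKKα shRNA CYP1A1 rose by 3.45, CYP1B1 by 1.80 and TIPARP by 0.79, while AHRR differed by -0.05 (adjusted p = 0.74).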
